A study of Mus musculus with 12 samples.

How the data were processed

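The series holds 12 single-cell RNA libraries of mouse small-intestinal crypts, 2 from each of 6 groups. The groups are wild type and a CRISPR-Cas9 knockout of PHF16, now named Jade3, each taken without irradiation (day 0) and at 3 and 7 days after whole-body irradiation. The labels give 12 Gy in one place and 10 to 16 Gy in another. Crypts were freed with EDTA, dissociated with TrypLE, and sorted for cells that exclude propidium iodide. The labels do not say whether the cells of 1 library come from 1 mouse or several, and they give no date or batch. A shared preparation day and the day after irradiation therefore cannot be told apart. The p-values below measure the spread between these libraries, which may be technical.

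The authors made the libraries with 10x 3′ chemistry and Cell Ranger. The submitters' processing notes name version 3.0.2 with build GRCm38, and the matrix headers name 3.1.0. The deposited matrices hold raw UMI counts per gene and barcode with no cell filter. Each lists 6794880 barcodes and 55421 gene identifiers, the same ones in all 12 libraries. The deposited gene lists hold other values than measurements, namely an identifier, a symbol and a feature type for each gene. The deposited barcode names were not used, only their position. Coordinates are those of GRCm38.

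The choices named here were made before the data were examined, except where stated otherwise. A barcode was taken as a cell with at least 2000 UMIs, at least 1000 genes and at most 20% of UMIs from mitochondrial genes. Scrublet was run per library with an expected rate of 5% and its own threshold. That threshold called next to no doublets at days 3 and 7, so doublets are in effect not removed there. Removing the 5% highest doublet scores of each library was therefore added after the data were seen. Under some alternatives, given below, the threshold moved and removed many cells of single libraries of day 7. The 54668 cells of all libraries were scaled to 10000 counts, log-transformed, reduced to 2000 variable genes and 30 principal components, and clustered with 15 neighbours and the Leiden method at resolution 1, with no batch integration (scanpy 1.11.5, leidenalg 0.10.2). The 35 clusters were named from 18 fixed marker lists by the lists' genes among the 50 most raised genes of the cluster. The thresholds of that naming were set after the data were seen. Of the epithelial clusters, 6 matched no list and are called unnamed epithelial, and their share is given for each group. Clusters with markers of immune, stromal, endothelial, glial or erythroid cells were set aside, which left 44701 epithelial cells.

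UMIs of the epithelial cells were summed per library. Their totals ran from 13134262 to 176554916. Genes were tested with edgeR 4.0.16 (TMM factors, filterByExpr, quasi-likelihood F-test) in 1 model of all 12 libraries with a term for each group, and p-values were adjusted by Benjamini-Hochberg over the 20394 genes tested. The threshold was an adjusted p of 0.05. Values in CPM are TMM-scaled group means of 2 libraries unless stated otherwise, and an error after ± on a log2 fold change is its standard error (SE). Contrasts were the knockout against wild type at each day, the mean of those 3 differences, each irradiated day against day 0 within a genotype, and the interactions of genotype with day. The same test was run within each cell class on libraries with at least 20 cells of the class. A day was tested for a class only where both groups kept 2 libraries. On simulated data with 200 changed genes, the test found 83.6% of the 2-fold changes at day 0, 70.1% at day 3 and 82.1% at day 7, and 11.9%, 13.4% and 6% of the 1.5-fold changes. The changed genes were drawn among those with a mean over 1 CPM and varied independently of each other. Calls there numbered 137, 128 and 135, which loosens the adjustment. Where few genes are called or counts are low, fewer such changes would be found, so few calls do not show that 2-fold changes are absent.

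The 27 fixed gene lists were tested with camera (limma 3.58.1) at the preset inter-gene correlation of 0.01, then with the correlation estimated, and with fry. Every call between genotypes at the preset correlation ended with the estimated one, so these calls rest on that preset. No list passed at the estimated correlation in any contrast. Counts of members are given over all genes tested and adjusted over the list alone. Cell numbers per class were tested with edgeR on counts, with the cells of the library as size. Shares of classes were compared by exact permutation, two-sided, with genotype permuted within days (216 assignments) or day within genotypes (8100 assignments), adjusted over 15 classes. With 2 libraries against 2, an exact test at a single day cannot reach 0.05; over the 3 days the smallest p it can give is 0.00926. Intervals and limits cover counting error only. In droplet data, free RNA adds UMIs to cells that do not express a gene.

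Genes named below follow a rule. They are the 8 highest and 8 lowest log2 fold changes among genes past the threshold with at least 10 CPM in the higher group and no overlap of the libraries. Added to these are the 4 members with the smallest p of each list past its test and of the stem, revival, YAP, Wnt and p53 lists, and Jade3, Jade1 and Jade2. Where fewer than 4 genes qualify, the 5 smallest p are named. Within classes the 4 highest and 4 lowest are named. The text names a part of these, and genes outside the rule are said to be chosen after their values were seen.

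Each result was computed again with DESeq2 1.42.0, without the filter on low counts, with a term for the replicate number, on the compared groups alone, with other minimums of UMIs and mitochondrial share, with doublets kept, with all cells of a library, with equal numbers of the 4 epithelial classes that every library held enough of (Paneth, enterocyte, enteroendocrine and goblet, without stem, transit-amplifying, revival, tuft and unnamed cells), at Leiden resolutions of 0.5 and 2, and without each library in turn. An alternative without clusters that 1 library gives over 80% of was added after the data were seen. Results used R 4.3.3 and Python 3.11.15. Barcodes of rank 20001 to 60000 by UMIs served as empty droplets.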

Results

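Single-cell transcriptomes of small-intestinal crypts were compared between wild-type and Jade3-knockout mice before irradiation and during regeneration at 3 and 7 days after it, with 2 libraries per group. Jade3 (PHF16) is a PHD-finger subunit of the HBO1 histone acetyltransferase complex. The libraries held 29336873 to 203604605 UMIs. Wild-type libraries gave 2802 and 3763 cells at day 0, 1780 and 2121 at day 3, and 6763 and 6915 at day 7. Knockout libraries gave 3629 and 2551, 2052 and 2612, and 9141 and 10539 cells. The median cell held 21837 to 28129.5 UMIs at day 0, 5959 to 6587.5 at day 3 and 15581 to 24350 at day 7. Epithelial cells made up 81.0% to 90.3% of a library at day 0, 15.9% to 20.4% at day 3, where most cells were T and NK cells, and 94.9% to 98.2% at day 7. Depth and epithelial share thus moved with the day in both genotypes.

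Jade3 transcripts were low in every knockout library, which was examined first as a check of the labels. Jade3 (ENSMUSG00000037315, chromosome X, 20425688 to 20519939, plus strand) was at 5.15, 4.81 and 6.43 CPM in wild-type epithelium at days 0, 3 and 7, and at 1.25, 1.95 and 1.52 CPM in the knockout. The log2 fold change, knockout over wild type, was -2.04 ± 0.16 at day 0 (adjusted p = 0.00126), -1.30 ± 0.18 at day 3 (adjusted p = 0.0533) and -2.08 ± 0.15 at day 7 (adjusted p = 0.000338). Over the 3 days it was -1.80 ± 0.09 (adjusted p = 1.85e-05), and -1.85 to -1.77 when any 1 library was left out. The day 0 call ended without replicate 2 of the knockout at day 0 (-2.03, adjusted p = 0.079), and the day 3 difference passed without replicate 1 of the knockout at day 3 (-1.25, adjusted p = 0.029). The site of the deletion is not given in the labels, and 3′ tags can still be read from a transcript that makes no protein. The paralogs Jade1 and Jade2 showed no called difference between genotypes, with log2 fold changes of 0.03 and 0.17 at day 0, 0.05 and 0.57 at day 3, and -0.27 and -0.01 at day 7. Without replicate 1 of the wild type at day 7, Jade1 was called at day 7 (-0.44, adjusted p = 0.017).

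The first comparison asked how the wild-type crypt changed by day 3. Genes of the revival and fetal-like list, which marks injured and regenerating epithelium, were far higher. Clu, a marker of revival stem cells, went from 0.49 to 206 CPM (log2 fold change 8.72 ± 0.42, adjusted p = 4.74e-07), and the tight-junction gene Cldn4 from 5.16 to 240 CPM (5.54 ± 0.23, adjusted p = 1.96e-07). Anxa1 reached 51.6 CPM and the interleukin-1 antagonist Il1rn 31.9 CPM, from under 0.04 CPM each. Of this list 27 of 29 members rose, with a median of 4.97 (adjusted p = 1.22e-17, and 0.0919 with an estimated correlation). YAP targets rose in 21 of 30 members, median 1.74 (adjusted p = 1.5e-08, and 0.0919 with an estimated correlation), among them the epidermal growth factor ligand Areg (6.41 ± 0.46) and the coagulation factor receptor F3 (5.24 ± 0.33). Of p53 targets 29 of 34 rose, median 1.81 (adjusted p = 6.07e-13, and 0.0919 with an estimated correlation). Phlda3 rose by 5.27 ± 0.17, Plk2 by 3.63 ± 0.13, Gdf15 by 4.46 ± 0.19 and the cell-cycle inhibitor Cdkn1a by 1.94 ± 0.11. Interferon response genes rose in 27 of 31 members, median 2.40 (adjusted p = 6.51e-12, and 0.287 with an estimated correlation), with Cxcl10 at 23.6 CPM against 0.489 (5.59 ± 0.44) and Mx1 at 11.2 against 1.05 CPM (3.42 ± 0.16).

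Proliferation, stem cell and respiratory genes were lower in the wild type at day 3. Of G2 and M phase genes 49 of 52 fell, median -2.58 (adjusted p = 4.79e-14, and 0.362 with an estimated correlation), and of S phase genes 42 of 44, median -1.84 (adjusted p = 3.79e-10, and 0.516 with an estimated correlation). Cenpf changed by -3.25 ± 0.20, Anln by -2.90 ± 0.18, Nusap1 by -2.51 ± 0.16 and the cell-cycle repressor E2f8 by -4.04 ± 0.33. Of 30 stem cell genes 15 fell and 5 rose (median -0.81, adjusted p = 0.166 against other genes). Among those lower were Smoc2 (-2.71 ± 0.19), Aqp4 (-3.17 ± 0.32) and Lgr5, the Wnt-responsive receptor of crypt-base stem cells (-2.35 ± 0.44, adjusted p = 0.00109). The Wnt target and adhesion receptor Cd44 rose, while the Wnt list as a whole had 8 members up and 6 down of 27. Oxidative phosphorylation genes fell in 33 of 35 members, median -1.22 (adjusted p = 4.43e-12, and 0.362 with an estimated correlation). Fatty acid oxidation genes fell in 16 of 22 members, median -1.09 (adjusted p = 0.000641, and 0.516 with an estimated correlation), with the thiolase Acaa2 at -2.37 ± 0.18. Jade1 fell by 0.74 on the log2 scale ± 0.12 (adjusted p = 0.000401). Jade2 was at -0.91 ± 0.24 (adjusted p = 0.00797), a call that ended without replicate 2 of the wild type at day 0 (-0.71, adjusted p = 0.063) or at day 3 (-0.82, adjusted p = 0.07). The fall was absent with equal numbers of 4 differentiated classes (0.009, adjusted p = 0.987) and turned with all called cells (1.53, adjusted p = 1.24e-05). Altogether 4256 genes were higher and 5955 lower, against 4960 and 4610 with DESeq2, at an adjusted p under the threshold, with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over 20394 genes. Lymphocyte markers read in the epithelial sums rose in 13 of 20 and myeloid markers in 7 of 12 members (medians 2.32 and 3.23), in libraries of which over 70% were T and NK cells.

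The knockout epithelium showed the same kinds of change at day 3. Clu was at 215 CPM (9.82 ± 0.46), Cldn4 at 212 CPM (5.39 ± 0.23), Anxa1 at 112 CPM and the calcium-binding protein S100a6 at 5134 CPM (5.73 ± 0.28). The revival list rose in 27 of 29 members, median 5.39 (adjusted p = 9.85e-18, and 0.0823 with an estimated correlation), YAP targets in 23 of 30, median 2.04 (adjusted p = 1.16e-08, and 0.0823 with an estimated correlation), and p53 targets in 29 of 34, median 1.94 (adjusted p = 1.4e-13, and 0.0823 with an estimated correlation). Phlda3 rose by 5.69 ± 0.17, Plk2 by 4.38 ± 0.14 and Gdf15 by 5.20 ± 0.20. Interferon genes rose in 27 of 31, median 3.49 (adjusted p = 6.13e-14, and 0.218 with an estimated correlation), with Cxcl10 at 63.3 against 0.128 CPM (8.85 ± 0.53) and Rsad2, an antiviral radical enzyme, at 137 against 1.19 CPM (6.84 ± 0.44). G2 and M phase genes fell in 49 of 52 (median -1.78) and S phase genes in 34 of 44 (median -1.01), with adjusted p = 0.442 and 0.606 with an estimated correlation. Olfm4, a Notch-dependent stem cell secreted protein, went from 840 to 12.2 CPM (-6.09 ± 0.88), and the glutathione transferase Gstm3 from 173 to 2.07 CPM (-6.41 ± 0.32). Jade3 itself was at 0.64 ± 0.18 (adjusted p = 0.0117), which ended without either knockout library of day 0 (0.63, adjusted p = 0.056 in both cases) and with equal numbers of 4 differentiated classes (0.14, adjusted p = 0.76). In all 4621 genes were higher and 5521 lower, an excess of lower genes that turned with DESeq2 (5110 and 4548) and with all called cells (6887 and 6377). Of the genes higher at day 3, 3558 were shared with the wild type where independent lists would share 964.1, and of those lower 4744, where 1612.1 would be shared. Only 2 genes moved in opposite directions.

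By day 7 the wild-type epithelium had kept part of the injury pattern and lost markers of differentiated cells. The resistin-like Retnlb went from 3.05 to 487 CPM (7.32 ± 0.87, adjusted p = 0.000106), Anxa10 from 0.339 to 48.4 CPM (7.15 ± 0.27), Lrg1 from 0.324 to 38.3 CPM (6.89 ± 1.10), Anxa1 to 41.7 CPM, and the antimicrobial lectin Reg3b from 1751 to 24710 CPM (3.82 ± 0.54, adjusted p = 0.0003). Of the revival list 26 of 29 members were above day 0, median 2.89 (adjusted p = 1.3e-10, and 0.583 with an estimated correlation), and Basp1, a member, was lower (-5.53 ± 0.27), though higher with equal numbers of 4 differentiated classes (4.41, adjusted p = 0.099). Ribosome biogenesis genes rose in 19 of 32 (median 0.70; adjusted p = 0.000196, and 0.908 with an estimated correlation), with nucleophosmin Npm1 at 1.70 ± 0.25 and nucleolin Ncl at 1.37 ± 0.23. Glutathione and Nrf2 genes rose in 14 of 26 (median 0.53; adjusted p = 0.000394, and 0.728 with an estimated correlation), with Gpx2 at 2.45 ± 0.31 and Gsta3 at 3.34 ± 0.30. Of tuft cell genes 20 of 20 fell, median -5.14 (adjusted p = 1.97e-11, and 0.583 with an estimated correlation), with the lipoxygenase Alox5 at -5.96 ± 0.29 and the taste channel Trpm5 at -5.55 ± 0.41. Enteroendocrine genes fell in 19 of 24 (median -1.84) and Paneth genes in 16 of 20 (median -2.21), with adjusted p = 0.583 and 0.805 with an estimated correlation. The lactase gene Lct changed by -4.63 ± 0.53, the granin Chga by -3.03 ± 0.31 and the defensin Defa26 by -4.03 ± 0.53. Interferon genes were now below day 0 in 23 of 31 members, median -1.36 (adjusted p = 2.08e-07, and 0.583 with an estimated correlation), as were 7 of 7 MHC class II genes, median -2.62 (adjusted p = 0.0019, and 0.728 with an estimated correlation). S phase genes were above day 0 in 19 of 44 members and below in 0 (median 0.61; adjusted p = 0.000394, and 0.908 with an estimated correlation). Of 52 G2 and M phase genes 7 were above day 0 and 5 below (median 0.09, adjusted p = 0.809). Jade1 remained lower (-0.49 ± 0.11, adjusted p = 0.0047). Of all genes 4984 were higher and 4821 lower.

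In the knockout at day 7, Retnlb stood at 819 CPM (8.53 ± 0.92), Lrg1 at 168 CPM (9.39 ± 1.19) and Anxa1 at 105 CPM. S100a6 rose by 4.93 ± 0.27, and the revival list in 26 of 29 members, median 4.47 (adjusted p = 2.7e-10, and 0.697 with an estimated correlation). The cystine transporter Slc7a11 rose by 5.73 ± 0.55, with glutathione and Nrf2 genes up in 14 of 26 members (median 0.71), and ribosome biogenesis genes rose in 27 of 32 (median 1.04), each with adjusted p = 0.712 with an estimated correlation. Paneth genes fell in 17 of 20 and tuft genes in 20 of 20, median -6.24, both with adjusted p = 0.712 with an estimated correlation. The defensin-like AY761184 went from 26750 to 436 CPM (-5.94 ± 0.63), Defa26 from 1189 to 22.3 CPM (-5.74 ± 0.57), the incretin Gip from 713 to 18.1 CPM (-5.30 ± 0.45) and Trpm5 from 22.7 to 0.205 CPM (-6.78 ± 0.45). Of 30 stem cell genes 14 were below day 0 and 3 above, among the latter Igfbp4 (1.62 ± 0.18). Jade1 was at -0.80 ± 0.11 (adjusted p = 0.000173). In all 5966 genes were higher and 6165 lower, with 4457 and 4385 shared with the wild type against 1457.4 and 1455.7 for independent lists, and 5 genes in opposite directions.

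Cell classes shifted with the day as well, though not all in step with these genes. By exact permutation within genotypes, 14 of 15 classes changed their share of all cells with day (adjusted p = 0.0037 to 0.027), B cells being the exception (adjusted p = 0.0667). As shares of epithelial cells, Paneth and goblet cells showed no change with day that passed (adjusted p = 0.945 and 0.916). While Paneth genes fell by day 7, Paneth cells went from 7.72% to 10.22% of epithelial cells in the wild type. In the knockout they went from 8.92% to 6.03%. The Paneth class lay mostly in cluster 19 at day 0. At day 7 it lay mostly in cluster 13, and in cluster 24 for replicate 2 of the knockout. Its median cell held 86540 to 137364 UMIs at day 0 and 12325 to 19130 at day 7, so each such cell added fewer UMIs to the sums. These shares may therefore not follow 1 kind of cell. Stem cells made up 18.2% ± 2.88 of wild-type cells at day 0 (SD, n = 2) and 23.1% ± 1.09 of knockout cells. At day 3 no cell of 687 wild-type and 886 knockout epithelial cells fell in that class. By counting alone this allows shares of up to 0.437% and 0.339%. Clusters followed the day, the stem class lying mostly in cluster 7 at day 0 and 16 at day 7. Stem cells of day 3 may thus stand in other classes. Transit-amplifying cells were 0.13% of wild-type and 0.06% of knockout epithelial cells at day 0. The G2 and M phase list had a mean log2(CPM + 1) of 5.056 to 5.243 there and 5.013 to 5.515 at day 7, so cycling cells of day 0 stood in other classes. The revival stem cell class held 0 cells at day 0, 14.8% ± 4.61 of wild-type and 21.5% ± 8.09 of knockout epithelial cells at day 3, and 3.24% ± 0.82 and 3.82% ± 0.82 at day 7. T and NK cells made up 75.4% ± 1.31 of wild-type and 72.4% ± 3.54 of knockout cells at day 3, and myeloid cells 6.03% ± 1.21 and 7.69% ± 1.67. Enteroendocrine cells were 5.95% ± 0.19 of wild-type epithelial cells at day 0, 19.1% ± 5.58 at day 3 and 3.21% ± 0.03 at day 7. Unnamed epithelial cells were under 0.2% of cells at days 0 and 3, and 22.8% ± 10.2 of wild-type and 45.4% ± 11.5 of knockout cells at day 7. Of the clusters that hold them, the one named 4 took 84.5% of its cells from replicate 2 of the knockout at day 7.

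**Figure D1:**
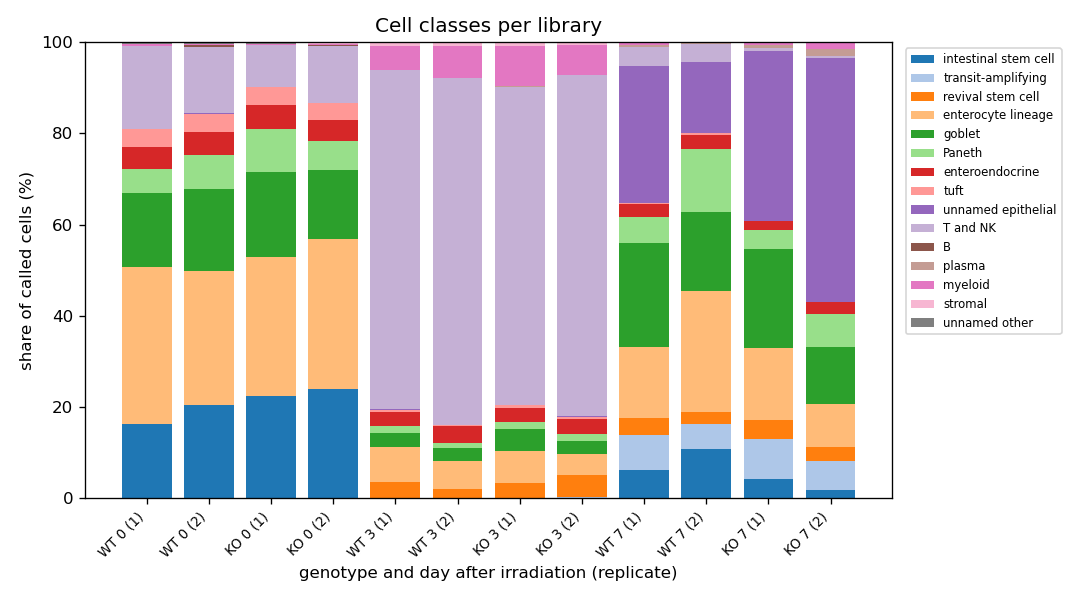
Share of the cells of each library in each class, in percent, as stacked bars, 1 bar per library, grouped by genotype and day. T and NK cells fill most of each bar at day 3, and unnamed epithelial cells hold 22.8% of wild-type and 45.4% of knockout cells at day 7 on average.

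The genotypes were then compared for cell classes, to ask whether loss of Jade3 alters the cells present before or after irradiation. At day 7 T and NK cells were 3.94% ± 0.23 of wild-type cells and 0.45% ± 0.04 of knockout cells (log2 fold change of counts -3.11 ± 0.36, adjusted p = 4.45e-05 with edgeR), and tuft cells 0.34% ± 0.16 and 0.07% ± 0.01 (-2.30 ± 0.58, adjusted p = 0.0156). Called cells of any class with at least 3 T and NK markers numbered 400 and 348 in the wild type and 177 and 374 in the knockout. Of these, 271 and 257 stood in the T and NK class in the wild type and 37 and 29 in the knockout, where unnamed epithelial clusters held 231 of those of replicate 2. Stem cells were 8.37% ± 3.29 and 2.94% ± 1.58 (-1.51 ± 0.48, adjusted p = 0.0594 of all cells; -1.54, adjusted p = 0.00373 of epithelial cells). Myeloid cells were at 0.34% ± 0.29 and 1.00% ± 0.55 (1.57 ± 0.64, adjusted p = 0.0992) and plasma cells at 0.37% ± 0.09 and 1.08% ± 0.62 (1.56 ± 0.54, adjusted p = 0.0727). No class was called at days 0 and 3. Those tests had no class at an unadjusted p under 0.05. Averaged over days, no class share passed the exact permutation test, the nearest being T and NK cells with -4.01 points (p = 0.0185, adjusted p = 0.278). A single class cannot pass that test, since its smallest p of 0.00926 is adjusted over 15 classes. With edgeR on counts, T and NK cells differed over the 3 days by -1.26 ± 0.19 (adjusted p = 0.000581). The tuft call ended without replicate 2 of the wild type (-1.71, adjusted p = 0.27) or of the knockout at day 7 (-2.55, adjusted p = 0.065), and the 2 calls became 4 without replicate 1 of the wild type, 5 without replicate 1 of the knockout, and 1 without replicate 2 of either at day 7. With at least 5000 UMIs per cell the T and NK difference was -2.60 (adjusted p = 0.057). In that setting Scrublet also removed 646 cells of replicate 2 of the wild type at day 7.

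Before irradiation, interferon response genes were lower in the knockout epithelium. The helicase Ddx60 was at 28.9 CPM in the wild type and 10.1 in the knockout (log2 fold change -1.52 ± 0.25, adjusted p = 0.162), Mx2 at 1.42 and 0.43 CPM (-1.72 ± 0.31), Ifi44 at 5.28 and 1.27 CPM (-2.06 ± 0.38) and Rsad2 at 5.04 and 1.19 CPM (-2.07 ± 0.40), none past the threshold over all genes. Adjusted over the list alone, 21 of 31 members fell (median -0.82, camera adjusted p = 2.94e-34, and adjusted p = 0.15 with an estimated correlation). MHC class II genes had a median of -0.73, with H2-Ab1 at 51.6 and 30.4 CPM and H2-Aa at 13.4 and 5.5 CPM, and none of 7 was called. Their mean log2(CPM + 1) was 4.27 and 4.50 in the wild type and 2.88 and 4.26 in the knockout, so replicate 1 of the knockout gave most of the difference. Enterocyte absorption genes had a median of -0.21 and goblet genes of -0.11, and Paneth genes a median of 0.31, G2 and M phase genes 0.13, early stress genes 0.06 and oxidative phosphorylation genes 0.07. The Paneth list mean was 10.229 and 10.295 in the wild type and 10.761 and 10.288 in the knockout, so its rise too lay in replicate 1. Apoa4, the chylomicron apolipoprotein, was at 1220 and 832 CPM (-0.55 ± 0.25), the lysozyme Lyz1 at 13850 and 17890 CPM (0.37 ± 0.24), Myc at 13.8 and 24.6 CPM (0.83 ± 0.28) and Nfkbia at 39 and 58.5 CPM (0.59 ± 0.13). Lymphocyte markers in the epithelial sums had a median of -0.45 (mean -0.23) and YAP targets -0.09. Oxidative phosphorylation genes turned direction without replicate 2 of the wild type at day 0 (camera adjusted p = 0.832), and lymphocyte genes without replicate 2 of the wild type (0.811) or of the knockout (0.484). These 10 lists passed camera at its preset, and all but the interferon list had adjusted p = 0.874 with an estimated correlation. Hoxb4 was at 0.588 and 2.39 CPM (2.02 ± 0.27), Trim30a at 8.9 and 2.69 CPM (-1.73 ± 0.26), and the alpha globin Hba-a1 at 14 and 0.336 CPM (-5.35 ± 0.73), with adjusted p = 0.132, 0.14 and 0.132. The only gene past the threshold was Jade3, with 636 genes at an unadjusted p under 0.05. DESeq2 called 40 genes, and the count was 2, 7, 2 and 0 without replicates 1 and 2 of the wild type and 1 and 2 of the knockout at day 0.

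At day 3 proliferation genes were higher in the knockout than in the wild type, mostly through replicate 2 of the knockout. The mean log2(CPM + 1) of S phase genes was 2.71 and 2.54 in the wild type and 2.83 and 3.65 in the knockout. That of G2 and M phase genes was 3.14 and 3.07 against 3.37 and 4.00. Replicate 2 of the knockout was also the only library of day 3 with transit-amplifying cells, 5 in number. Anln, the actin-binding anillin needed for cytokinesis, was at 8.12 CPM in the knockout and 1.85 in the wild type (2.14 ± 0.18, adjusted p = 0.00323) and was the only gene called. Kif23, the motor of the central spindle, was at 15.8 and 7.16 CPM (1.15 ± 0.16, adjusted p = 0.0533), Mki67 at 20.7 and 8.57 CPM (1.27 ± 0.27) and Top2a at 30.9 and 14.8 CPM (1.07 ± 0.23). Adjusted over the list alone, 30 of 52 G2 and M phase genes rose (median 0.78, camera adjusted p = 7.55e-12) and 31 of 44 S phase genes (median 0.83, camera adjusted p = 1.32e-09). Ribosome biogenesis genes had a median of 0.52, with Ncl at 394 and 247 CPM (0.68 ± 0.23), p53 targets 0.19, with Gdf15 at 78.5 and 42.3 CPM (0.89 ± 0.16), and oxidative phosphorylation genes 0.14, which turned direction without replicate 2 of the wild type at day 3 (camera adjusted p = 0.89). Enterocyte genes had a median of -0.58, with the fatty acid binding protein Fabp2 at 1982 and 3779 CPM (-0.93 ± 0.30), Alpi at 118 and 221 CPM (-0.91 ± 0.27) and the cholesterol transporter Npc1l1 at 46.4 and 75 CPM (-0.69 ± 0.18). The enteroendocrine list had a median of -0.50 and a mean of 0.01, with ghrelin Ghrl at 1905 and 610 CPM (1.64 ± 0.40) and Cck at 1656 and 3162 CPM (-0.93 ± 0.35). These 7 lists passed camera at its preset, each with adjusted p = 0.996 with an estimated correlation. The angiopoietin-like Angptl4 was at 18.3 and 6.06 CPM (1.59 ± 0.20, adjusted p = 0.0533) and Cebpd at 27.3 and 14.2 CPM (0.94 ± 0.12, adjusted p = 0.0533), and in the revival list Anxa1 at 112 and 51.6 CPM (1.12 ± 0.36). Of all genes 2892 had an unadjusted p under 0.05 and DESeq2 called 260. The count was 556 without replicate 1 of the knockout at day 3, 5 without its replicate 2, 4 and 2 without replicates 1 and 2 of the wild type at day 3, and 10 without either wild-type library of day 7. The Anln call ended on the compared groups alone (2.05, adjusted p = 0.26) and with equal numbers of 4 differentiated classes (2.59, adjusted p = 0.58).

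At day 7 revival genes were higher, and Paneth, enteroendocrine and interferon genes lower, in the knockout. The wild-type pair had a chi-square per degree of freedom of 427.26 on counts, against 75.47 in the knockout pair of day 7 and 28.97 to 70.08 in the other groups. This measure rises with depth, and only the knockout pair of day 7 was as deep. The wild-type pair thus stood further apart than the knockout pair, while the shallower groups cannot be ranked against it. The mean log2(CPM + 1) of the revival list was 4.443 and 3.98 in the wild type and 4.685 and 4.954 in the knockout. That of the Paneth list was 7.31 and 8.81 against 6.78 and 7.37, so its libraries overlapped. Those of the enteroendocrine and interferon lists did not overlap. Of the revival list 17 of 29 members rose adjusted over the list alone (median 0.78, camera adjusted p = 5.02e-09, and adjusted p = 0.526 with an estimated correlation). Anxa1 was at 105 CPM in the knockout and 41.7 in the wild type (1.33 ± 0.35), the urokinase receptor Plaur at 16.4 and 6.59 CPM (1.31 ± 0.32) and Il1rn at 4.46 and 1.95 CPM (1.20 ± 0.26). Stem cell genes fell in 7 of 30 members over the list alone (median -0.34), with Rgmb at 18.7 and 30 CPM (-0.68 ± 0.15), Clca3b at 40.3 and 86.4 CPM (-1.10 ± 0.27) and Vdr at 21.4 and 41.2 CPM. Wnt targets had a median of -0.32, with Axin2 at 18.3 and 27.4 CPM (-0.58 ± 0.17) and Lgr5 at 3.92 and 7.92 CPM (-1.01 ± 0.37). Paneth genes fell in 14 of 20 (median -1.11), with the ribonuclease Ang4 at 103 and 362 CPM (-1.81 ± 0.43) and the lectin Itln1 at 1425 and 3046 CPM (-1.10 ± 0.29). Enteroendocrine genes fell in 14 of 24 (median -0.88), with Gip at 18.1 and 86.7 CPM (-2.26 ± 0.39) and Chga at 8.45 and 23.4 CPM (-1.47 ± 0.30). Interferon genes fell in 19 of 31 (median -0.66), with Oas2 at 0.137 and 0.709 CPM (-2.38 ± 0.36), Ifi27 at 15.7 and 31.1 CPM (-0.98 ± 0.17) and Ddx60 at 2.01 and 5.13 CPM (-1.35 ± 0.26). Enterocyte genes fell in 12 of 34 (median -0.60), with Khk at 63.4 and 121 CPM and Sis at 222 and 417 CPM, goblet genes in 9 of 20 (median -0.46), and tuft genes in none of 20 (median -0.94). Each of these had adjusted p = 0.526 with an estimated correlation. For enterocyte genes replicate 1 of the wild type (mean 6.25) lay nearer to the knockout (6.11 and 6.04) than to replicate 2 of the wild type (6.93). Paneth cells were 10.22% of wild-type and 6.03% of knockout epithelial cells, enterocytes 22.15% and 12.91%, and unnamed cells 23.96% and 46.72%. Sums over all epithelial cells do not part such shifts from changes within cells.

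Further lists passed camera at day 7. Ribosome biogenesis genes had a median of 0.46 (camera adjusted p = 9.08e-10), with Ddx21 at 152 and 104 CPM, S phase genes 0.34, G2 and M phase genes 0.35, unfolded protein genes 0.20, cholesterol synthesis genes 0.15, which turned direction without replicate 2 of the wild type at day 7 (camera adjusted p = 0.000162), fatty acid oxidation genes -0.30 and early stress genes -0.23. Glutathione and Nrf2 genes had a median of 0.26 (0.255 before rounding), with Slc7a11 at 13.6 and 4.65 CPM (1.54 ± 0.40) and heme oxygenase Hmox1 at 7.08 and 3.41 CPM (1.04 ± 0.37), and myeloid markers in the epithelial sums 0.56, with C1qa at 1.75 and 0.308 CPM. With an estimated correlation these had adjusted p = 0.526, except S phase genes (0.528) and cholesterol synthesis genes (0.664). For S phase genes replicate 1 of the wild type (mean log2(CPM + 1) of 5.03) lay nearer to the knockout (5.10 and 5.15) than to replicate 2 (4.545). The p53 targets Btg2 (-0.71 ± 0.13) and Trp53inp1 (-1.11 ± 0.28) were lower while that list's median was 0.00.

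Single genes called at day 7 were 4. The processed copies of the chaperone gene Hspa8, Gm8326 (28.0 against 0.225 CPM, 6.94 ± 0.24, adjusted p = 1.76e-07) and Gm15459 (8.49 against 0.708 CPM, 3.58 ± 0.34, adjusted p = 0.00276), were read in the knockout at day 7 and next to absent at days 0 and 3. Jade3 was the third, and the neutrophil chemokine Cxcl2 the fourth (4.07 against 0.888 CPM, 2.19 ± 0.28, adjusted p = 0.0471). The Cxcl2 call ended in 16 of 24 alternatives, among them those without replicate 2 of the wild type (2.12, adjusted p = 0.18) or of the knockout at day 7 (1.97, adjusted p = 0.36), and that of Gm15459 without replicate 2 of the wild type at day 7 (3.41, adjusted p = 0.054). On the compared groups alone Gm8326 kept its call, while Gm15459 (3.56) and Jade3 (-2.09) had adjusted p = 0.0525 each. With equal numbers of 4 differentiated classes Gm15459 was at 3.94 (adjusted p = 0.185). Of all genes 3824 had an unadjusted p under 0.05, and DESeq2 called 782. The count was 2762 without replicate 1 of the wild type at day 7, 2 without its replicate 2, and 31 without replicate 1 of the knockout at day 7.

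On the mean of the differences at the 3 days, 20 genes were higher and 52 lower in the knockout. Such a mean need not hold at each day, and Ddx60 was at -0.07 at day 3 and Anln at 0.10 at day 0. Interferon-induced genes were among the lower ones. Oas2 changed by -1.42 ± 0.18 (adjusted p = 0.0208), Trim30a by -1.22 ± 0.16 (adjusted p = 0.0233), Ifi44 by -1.42 ± 0.22, Oasl2 by -1.01 ± 0.17, Ddx60 by -0.98 ± 0.14 and the regulator Irf7 by -0.78 ± 0.13. Of the list's 31 members 6 fell over all genes tested and 24 adjusted over the list alone (median -0.42, camera adjusted p = 1.46e-13, and adjusted p = 0.804 with an estimated correlation). Apol10a (-1.23 ± 0.18), the sodium channel Scn3a (-0.91 ± 0.16), the brush-border protease Mep1a (-0.78 ± 0.13), the serotonergic factor Fev (-0.71 ± 0.11) and Fabp5 (-0.57 ± 0.10) were lower too. The metallothioneins Mt2 (1.16 ± 0.15, adjusted p = 0.0233) and Mt1 (0.91 ± 0.13, adjusted p = 0.0297), which bind zinc and copper, were higher, Mt2 at 9.36 and 18.9 CPM in wild type and knockout at day 0, 48.5 and 144 at day 3, and 131 and 245 at day 7. The aldo-keto reductase Akr1b8 (0.72 ± 0.12), the forkhead factor Foxq1 (0.58 ± 0.08), Apobec3 (0.47 ± 0.07), Anln (0.91 ± 0.09) and Kif23 (0.58 ± 0.08) were higher as well. Adjusted over the list alone, 38 of 52 G2 and M phase genes (median 0.43) and 29 of 32 ribosome biogenesis genes (median 0.35) rose, and 22 of 34 enterocyte genes (median -0.46) and 15 of 24 enteroendocrine genes (median -0.56) fell, with adjusted p = 0.804, 0.854, 0.804 and 0.804 with an estimated correlation. Chosen after their values were seen, Hoxb2 (2.00 ± 0.29), Hoxb3os (1.96 ± 0.28), Hoxb4 (1.40 ± 0.17) and Hoxb7 (1.65 ± 0.25), all under 4 CPM, were higher, and the phosphate transporter Slc34a2 lower (-1.88 ± 0.29).

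These 72 calls lay close to the threshold, and the call over the 3 days of each gene named except Jade3 and Anln ended without at least 1 library. The count was 8 and 27 without replicates 1 and 2 of the wild type at day 0, 3 and 8 without those of the knockout at day 0, 4 without replicate 2 of the wild type at day 3, 1267 and 24 without replicates 1 and 2 of the knockout at day 3, 2570 without replicate 1 of the wild type at day 7, and 17 and 2 without those of the knockout at day 7. The balance of directions did not hold either, with 692 genes higher and 662 lower with DESeq2, 851 and 416 without replicate 1 of the knockout at day 3, and 1471 and 1099 without replicate 1 of the wild type at day 7. None of the 72 turned direction in any of these, and 4320 genes had an unadjusted p under 0.05.

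Whether the response to irradiation differs between genotypes was tested by interaction. Anln fell less by day 3 in the knockout (interaction 2.04 ± 0.23, adjusted p = 0.0466), and Gm8326 rose by day 7 in the knockout alone (6.59 ± 0.54, adjusted p = 0.00185). No other gene passed, with 1045 and 1568 genes at an unadjusted p under 0.05 for days 3 and 7 and 17 and 38 called by DESeq2. Interferon genes had a day 3 median of 0.92, 16 of 31 members rising adjusted over the list alone (adjusted p = 0.962 with an estimated correlation), among them Rsad2 (2.59 ± 0.52), Cxcl10 (3.26 ± 0.73) and Ddx60 (1.45 ± 0.34). At day 7 the revival list had a median of 0.64 with an estimated-correlation adjusted p = 0.551, and no member called, with Ly6a at 2.57 ± 0.73, Plaur at 1.84 ± 0.53 and S100a6 at 1.06 ± 0.32. Paneth genes had a median of -1.56 and stem cell genes of -0.38, each with adjusted p = 0.625 with an estimated correlation, with Ang4 at -2.18 ± 0.59 and Clca3b at -1.49 ± 0.38. The T and NK class fell further in the knockout by day 7 (-2.51 ± 0.47, adjusted p = 0.00368), a call on the class counts given above. This call was not computed on cells of any class with T and NK markers. It ended without replicate 2 of the wild type at day 0 (-2.36), with at least 5000 UMIs (-1.06, adjusted p = 0.586) and with doublets kept (-1.86, adjusted p = 0.0572). Keeping doublets added 15 to 48 cells to a library of day 0 and 0 to 5 to one of day 7, and the cells were clustered anew. The Anln call ended when any of 10 libraries was left out, namely all but those of the wild type at day 7. The count was 2 without replicate 2 of the knockout at day 3 or either wild-type library of day 7. That of Gm8326 ended without replicate 2 of the wild type at day 0 (6.23, adjusted p = 0.25), and without replicate 1 of the wild type at day 7 the count was 457.

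Within cell classes, the interferon difference before irradiation was found in enterocytes and goblet cells. In the enterocyte lineage (mostly clusters 12 and 15) Apol9a changed by -1.78 ± 0.26, Oas3 by -1.70 ± 0.25, Trim30a by -1.68 ± 0.26 and Ddx60 by -1.65 ± 0.22, with adjusted p = 0.0286 each. In goblet cells (mostly cluster 9) Apol9a was lower (adjusted p = 0.00274), and Apol9b changed by -1.85 ± 0.27, Ifit1 by -1.81 ± 0.26 and Oas3 by -1.63 ± 0.18. Phlda1, a gene of the stem and regenerating crypt, was higher in enterocytes (2.32 ± 0.34). In stem cells Jade3 was the only call (-2.42 ± 0.25). Enteroendocrine cells held more Hoxb4 (1.87 ± 0.29), the retinol-binding Rbp7 (1.96 ± 0.29) and Dmbt1 (1.22 ± 0.17). Tuft cells had 31 calls on 5 libraries, 28 of them higher, among these enterocyte genes such as Rbp2 (2.27 ± 0.25) and Ces2c (2.37 ± 0.26). Globins were lower in Paneth cells (Hbb-bs at 3.11 against 345.5 CPM), and the mast cell proteases Mcpt1 and Mcpt2 higher in the T and NK class (473 against 0.554 CPM for Mcpt1), which are markers of other cell types. These 84 calls became 45 and 162 without replicates 1 and 2 of the wild type at day 0, 55 and 235 without those of the knockout, and 180 and 177 without replicates 1 and 2 of the wild type at day 7.

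At day 3, enteroendocrine cells of the knockout held more Ghrl, at 20860 against 5622 CPM (1.89 ± 0.29, adjusted p = 0.0301), S100a16 (2.28 ± 0.22, adjusted p = 0.000943), and Itln1 (2.58 ± 0.37), and less of the protease gene Bace2 (-1.46 ± 0.24) and the interferon-induced Ifit1bl1 (-1.31 ± 0.22). Revival stem cells (cluster 17) held less of the chemokine Ccl20 (-5.93 ± 0.66, adjusted p = 0.0122) and the guanylin Guca2a (-2.68 ± 0.26) and more Apoa4 (2.38 ± 0.22). T and NK cells gave 35 calls, 9 of them lower, among these the enterocyte genes Fabp2 (-1.43 ± 0.22) and Rbp2 (-1.14 ± 0.19). Myeloid cells gave 16, mostly epithelial genes lower such as Krt18 (-3.75 ± 0.38). Paneth, enterocyte and goblet cells had 0 calls with edgeR, and 724, 1075 and 1060 genes at an unadjusted p under 0.05. The 68 calls became 115 and 306 without replicates 1 and 2 of the wild type at day 3 and 140 without replicate 2 of the knockout.

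At day 7, the hormone gene Gip was lower within enteroendocrine cells, at 702 against 3117 CPM (-2.15 ± 0.34, adjusted p = 0.0217), with the cannabinoid receptor Cnr1 (-3.64 ± 0.47), the irritant channel Trpa1 (-2.49 ± 0.39) and the defensin Defa34 (-4.38 ± 0.59), while Tff1 (3.07 ± 0.48) and the snoRNA host gene Snhg3 (1.56 ± 0.23) were higher. The Paneth list in empty droplets was lower in the knockout too, at 10986 and 14312 CPM against 21692 and 34291. Whether free RNA gives the Defa34 change was not tested. Goblet cells (clusters 2 and 10) held less Ifi27 (-0.88 ± 0.12), and enterocytes (clusters 6 and 8) less Ifi27 (-0.88 ± 0.13), Fbp1 (-1.46 ± 0.20) and Gpd1l (-0.81 ± 0.10) and more Snhg3 (0.94 ± 0.12) and the centromere gene Cenpw (0.84 ± 0.12). The cells of the knockout placed in the T and NK class, 89 against 538, held less Trac (-1.82 ± 0.31), Fasl (-1.94 ± 0.34) and Trgv2 (-2.12 ± 0.39), and more of the leukotriene receptor gene Ltb4r1 (4.49 ± 0.88) and Ramp3 (4.98 ± 1.03). Stem cells (cluster 16) and plasma cells had 0 calls, with 1804 and 370 genes at an unadjusted p under 0.05. Gm8326 was called in every epithelial class tested at day 7 except stem cells. The 125 calls became 7754 and 266 without replicates 1 and 2 of the wild type at day 7 and 3834 without replicate 1 of the knockout at day 7.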

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

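The tests of carried-over immune cells, of Hspa8 reads in each replicate and of a variant of the whole knockout line were chosen only after the result was seen.

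Anln differed between genotypes in its response by day 3, with an interaction of 2.04 on the log2 scale. It went from 13.7 to 1.85 CPM in the wild type and from 14.7 to 8.12 CPM in the knockout.

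The processed Hspa8 copy Gm8326 differed in its response by day 7, with an interaction of 6.59, and Gm15459 was read in the same libraries. Gm8326 lies on chromosome 1 (46414502 to 46416932) and shares 475 of its 1923 stretches of 31 bases with Hspa8. Gm15459 on chromosome 5 (5781615 to 5783555) shares 1756 of 1911. In replicate 1 of the knockout at day 7 the UMIs of Gm8326 per UMI of Hspa8 differed by 1.14-fold between epithelial classes while its CPM differed by 2.69-fold, so reads of Hspa8 assigned to the copy at 1 rate in all cells remain a candidate source there. In replicate 2 that ratio differed by 15.87-fold, which argues against 1 rate in all cells of that library, and the highest level at days 0 and 3 was 4.98% of the lowest at day 7, which argues against a variant shared by the whole knockout line. The 1924 cells of 5 clusters in replicate 2 with a low ratio held Jade3 at 1.098 CPM of all UMIs (36 UMIs, 95% interval 0.769 to 1.52), against 1.5 CPM in its other cells and 1.40 in replicate 1, which argues against wild-type cells. A mixture of knockout animals that differ at the locus of Hspa8 or its copies may account for replicate 2 and was not tested.

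The T and NK class fell further in the knockout than in the wild type between days 0 and 7, with an interaction of -2.51 on class counts. Fewer immune cells of every kind carried along is argued against, since myeloid and plasma cells lay at least 6.34 combined SE above the T and NK class. Counting all barcodes of at least 500 UMIs with 3 T and NK markers, the log2 ratio of knockout to wild type per called cell was -0.49, only just above the bound of -0.5 set before, so the minimum of UMIs per cell may account for a part of the loss. Such barcodes numbered 10.4 and 11.05 per 100 called cells in the wild type and 9.28 and 5.96 in the knockout, and with at least 2000 UMIs 6.02 and 5.28 against 2.00 and 3.57. At day 0 they numbered 28.5 and 24.1 per 100 called cells in the wild type and 14.9 and 17.3 in the knockout. With at least 2000 UMIs they were 24.1 and 19.5 against 11.8 and 14.6. By this count the knockout lay below the wild type before irradiation too, so the interaction of the class counts may not hold for T and NK cells. Of 374 called cells with such markers in replicate 2 of the knockout, 29 stood in the class and 231 in unnamed epithelial clusters, and how far that placement makes the class difference was not tested, so a smaller number of T and NK cells stays open.

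Empty droplets enter none of the gene comparisons between groups. In both genotypes several lists took a larger share of their UMIs, in CPM, after irradiation than before it. This is no measure of amount, since these droplets held 1048199 to 1606997 UMIs per library at day 3 and 2555234 to 3608385 at day 0. The lowest library of day 3 exceeded the highest of day 0 by 4.9-fold for the revival and fetal-like list, by 4.73-fold for lymphocyte markers, by 5.91-fold for myeloid markers and by 6.53-fold for stromal, endothelial and glial markers. At day 7 the antimicrobial Reg list exceeded it by 4.14-fold. Groups of 2 libraries are too small for a test of single libraries that stand apart, though the spread of pairs of like depth can be compared. The wild type at day 7 had a wider spread than the knockout at day 7, with a chi-square per degree of freedom of 427.26 against 75.47. The other groups had 28.97 to 70.08, but they were shallower and this measure rises with depth.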

How the results depend on the processing

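Removing the 5% highest doublet scores and leaving out clusters that 1 library gives over 80% of were chosen only after the result was seen. The fall of Jade3 over the 3 days kept its direction and its call in every alternative, and the total counts of genes that respond to irradiation stayed within 1.5 times except where named here. Class shares that differ between genotypes stayed at 0, which says little, since 1 class alone cannot pass that test. The replicate block adds the replicate number to the model; differences between replicates 1 and 2 correlated across groups at -0.122 to 0.102 over genes, so the numbers do not pair the libraries. The cause of each change below was not tested, except that fewer cells or libraries lower the power and testing more genes changes the adjustment. Where 1 library is left out, the lone library is assumed to vary like the other groups.

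Genes called between genotypes at days 0, 3 and 7 and over all days were 1, 1, 4 and 72. Without the filter they were 227, 1062, 2081 and 2270, and with DESeq2 40, 260, 782 and 1354. The replicate block gave 5 and 3 at days 0 and 3. On the compared groups alone they were 39, 0 and 2, and that was not run over all days. Equal numbers of 4 differentiated classes gave 7 at day 0, 0 at day 3 and 15 over all days, and all called cells gave 7 at day 3, 288 at day 7 and 381 over all days. Over all days at most 10% mitochondrial UMIs gave 40, and removing the highest doublet scores 25. At that mitochondrial limit Scrublet's own threshold also moved. It removed 750 cells (11.97%) of replicate 2 of the wild type and 1362 (16.01%) of replicate 1 of the knockout at day 7. With at least 5000 UMIs it removed 646 (10.58%) of replicate 2 of the wild type at day 7. These 2 alternatives thus changed more than the limit they name. Leaving out 1 library gave 0 to 7, 1 to 556, 2 to 2762 and 2 to 2570.

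The interactions, 1 gene each, gave 256 and 540 without the filter and 17 and 38 with DESeq2. That of day 3 gave 0 with the replicate block, at least 5000 UMIs, at most 10% mitochondrial UMIs, doublets kept, the highest doublet scores removed, all called cells or the compared groups alone, and 2 with equal numbers of 4 classes. That of day 7 gave 0 with equal numbers of 4 classes. Leaving out 1 library gave 0 to 2 and 0 to 457. Equal numbers of 4 classes lowered the irradiation counts to 6181 and 5166 in the wild type and 6303 and 6197 in the knockout at days 3 and 7. That setting held fewer cells and genes and also fixed the mix of classes, and the part of each was not tested. At day 3 the 4256 genes higher and 5955 lower in the wild type became 4960 and 4610 with DESeq2 and 6696 and 6374 with all called cells, most of which are T and NK cells. In the knockout 4621 and 5521 became 5110 and 4548 with DESeq2 and 6887 and 6377 with all called cells. In the wild type the 5955 lower at day 3 became 3520 without its replicate 2 of day 3, and the 4984 higher at day 7 became 3277 and 3184 without its replicates 1 and 2 of day 0. With all called cells, 1060 of 10211 calls in the wild type and 765 of 10142 in the knockout turned direction, and with equal numbers of 4 classes 389 and 370.

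Within classes, where clusters of 1 library were not left out, 84, 68 and 125 calls became 1142, 1649 and 5057 without the filter, 165, 183 and 926 with DESeq2, and 294, 116 and 57 on the compared groups alone. Keeping doublets gave 43, 33 and 1380. At day 7 that added only 0 and 5 cells to the wild-type and 3 and 0 to the knockout libraries, and all cells were clustered anew. So few cells argue against doublets themselves as the source of the 1380 calls, and cells moved between classes by the new clustering remain a candidate. At least 5000 UMIs gave 20 and 33 at days 0 and 7, and removing the highest doublet scores 32 at day 0. At most 10% mitochondrial UMIs gave 40 at day 3, the replicate block 247 and at least 1000 UMIs 68 at day 7. Leiden resolution 0.5 gave 38 and 1570 at days 3 and 7, and resolution 2 gave 45 at day 3. Leaving out 1 library gave 45 to 235, 48 to 306 and 120 to 7754.

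The 2 classes called became 1 with at least 1000 UMIs, 4 at Leiden resolution 0.5, 5 at resolution 2 and 5 without clusters of 1 library, and 1 to 5 without 1 library. As shares of epithelial cells 7 of 9 classes changed with day, and Paneth (adjusted p = 0.945) and goblet cells (0.916), which passed as shares of all cells, did not. The 35 list calls between genotypes became 0 with an estimated correlation and 1 with fry, a list that holds Jade3 itself. Of the genes and lists named, few reversed. Jade2 at day 3 was at 1.53 with all called cells and 0.009 with equal numbers of 4 classes in the wild type, and at 1.28 with all called cells in the knockout. Basp1 at day 7 was at 4.41 and 2.94 with equal numbers of 4 classes in wild type and knockout. Lists turned direction when a library of the day compared was left out. Oxidative phosphorylation did so without replicate 2 of the wild type at day 0 (adjusted p = 0.832) and at day 3 (0.89). Lymphocyte genes at day 0 did so without replicate 2 of the wild type (0.811) or of the knockout (0.484). Cholesterol synthesis at day 7 did so without replicate 2 of the wild type (0.000162). Over all libraries left out, the adjusted p of oxidative phosphorylation ran from 0.000596 to 0.832 at day 0 and from 0.000184 to 0.89 at day 3. That of lymphocyte genes ran from 2.67e-07 to 0.811 and that of cholesterol synthesis from 2.33e-10 to 0.133. For the named genes, 3004 calls under other settings stayed as they were, 179 newly passed the threshold and 77 no longer did. Without 1 library these were 3018, 77 and 205. Depth was lowest at day 3, with 13134262 to 24447357 epithelial UMIs per library.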

Other observations

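The X-linked and permuted-list comparisons, the class-mix test of the interferon genes and the counts of other splits were chosen only after the result was seen.

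Hormone, antimicrobial and heat shock genes also moved with irradiation. Enteroendocrine genes rose by day 3 in 18 of 24 members in the wild type and 16 of 24 in the knockout (median 2.11; adjusted p = 0.442 with an estimated correlation). Tph1, the serotonin-making hydroxylase, rose by 3.49 ± 0.35 and the granin Chga by 3.13 ± 0.31 in the knockout. Of 18 antimicrobial genes 11 rose and 4 fell in the wild type at day 3 (median 2.93, adjusted p = 0.552 with an estimated correlation), with the lectin Reg4 at 2.95 ± 0.24 and the scavenger receptor Dmbt1 at -4.80 ± 0.32. Immediate early and heat shock genes rose in 19 of 28 members (median 1.02, adjusted p = 0.158 with an estimated correlation), and unfolded protein genes fell in 13 of 21 (median -0.61, adjusted p = 0.734 with an estimated correlation). Of the JADE and HBO1 complex 10 of 14 genes fell at day 3 in the wild type and 7 in the knockout (adjusted p = 0.292 and 0.382 with an estimated correlation). At day 7 the oxidase Duox2, which makes hydrogen peroxide at the mucosa, stood at 2.87 ± 0.34 above day 0 in the wild type and 2.65 ± 0.33 in the knockout.

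Interferon genes were lower in the knockout epithelium at day 0. Free RNA gave at most 1.85% of the difference in enterocytes over the pairings of libraries, and empty droplets held 1077 and 1062 CPM of the list in the wild type and 623 and 822 in the knockout. A different mix of classes is argued against by medians of -0.943 or lower within enterocytes and within goblet cells. The difference may thus lie within the cells. Whether it belongs to the genotype or to the housing and microbes of the mice was not tested and stays open.

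Genes of the Hoxb cluster were higher in the knockout. A different stretch of intestine is argued against at day 0 by a knockout minus wild-type difference of 0.01 in distal minus proximal transcripts of enterocytes, which was -0.13 at day 3 and 0.43 at day 7. Of the distal genes, Fabp6, Slc10a2, Fgf15 and Plb1 were at 0.87 CPM or lower in both genotypes at day 0. They could rise but hardly fall, so the score is less able to show a more proximal stretch. At day 7 the libraries overlapped, at -3.52 and -4.23 in the wild type and -3.57 and -3.32 in the knockout. The median over classes of the median Hoxb change was 0.37, between the bounds set before, with all 9 class medians above 0, from 0.109 to 0.651. Hoxb4 was called at day 0 within enteroendocrine cells (1.87) and goblet cells (2.56), a difference that the shares of the classes do not enter. For the other members the part that a different mix of classes gives stays open. Of the genes lower in the knockout over all days, 50 remain without Jade3 and without genes that have no position in the gene annotation, and 4 of these lie on chromosome X, namely Armcx3 (-0.54), Bhlhb9 (-1.05), Arxes2 (-1.71) and Bex2 (-0.69), which is 8.0% against 2.91% of 19978 other tested genes with a position, a difference that was not tested.

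Other splits of the 12 libraries within days were drawn 100 times, the real one included. For genes called between genotypes over all days, 1 of 100 splits reached 72, the real one, and the highest of the others had 1. Nearly all other splits part libraries of the same group, which widens the spread if those share a mouse or preparation. Those that keep the groups whole are too few to exclude chance as the source of that count. For gene lists, 52 of 100 reached the real count of 11 and the highest other had 17, so chance cannot be excluded there either. By exact permutation of genotype within days, the mean of G2 and M phase genes differed by 0.343 and that of enterocyte genes by -0.425, each with an adjusted p of 0.125.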
